A study of Homo sapiens with 2 samples.

How the data were processed

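RNA from MDA-MB-231 cells, an established human triple-negative breast cancer line, was measured on 2 Affymetrix U133 Plus 2.0 arrays. 1 array came from cells transfected for 48 h with a control siRNA and 1 from cells transfected for the same time with siRNA against KMO, per the labels' protocols. Each array therefore stands for 1 culture condition with no replicate, and no test between conditions and no p-value was computed. The titles, genotype and treatment labels name siRNA, whereas the array names in the description field carry the strings shLUC and shK421, which are usual for short hairpin constructs. The grouping follows the titles.

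The deposited values are on a log2 scale after robust multi-array averaging (RMA), per the labels, and the submitters' processing notes name Affymetrix Expression Console. RMA corrects the background of each array, quantile normalizes the arrays together and summarises the probes of a probe set into a single level. Such values have no detection call and no true zero, so a weak probe set sits at a background level instead of at 0, and differences of weakly expressed genes are compressed. The version of the software and the set of arrays normalized together are not given in the sources used here. The sorted values of both columns differed little, with a widest gap at any rank of 0.064 log2 units, with medians of 4.44 in the control array and 4.43 in the siKMO array, so a shift shared by all transcripts could not be seen. Of the 54675 probe sets, 5171 (9.46%) had identical values on both arrays, at a median level of 2.94. No detection counts exist for arrays, and the number of arrays limits the precision.

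Probe sets were named through the platform's annotation, with symbols updated by gene identifier against a RefSeq gene table of assembly GRCh38.p14. Of the 42892 listed probe sets other than array controls, 41091 carried 1 gene and 1801 carried several; the latter named no gene. Of those with 1 gene, 41037 were matched by gene identifier and 54 kept the symbol of the annotation. A further 11721 probe sets were not listed there and are unnamed here, and 62 were array controls. The named probe sets covered 19775 genes. Chromosomal positions are not printed, since the sources name no genome build, and the RefSeq table served only for names and for which genes neighbour each other.

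The value of a gene was that of its probe set with the highest mean over both arrays, and a gene counted as measured where that mean was at least 6 on the log2 scale, which left 8997 genes. The level of 6 is a round minimum, and 19 of 21 genes of unrelated tissues lay under it. A gene or probe set can pass it with 1 array under 6; its folds and differences are then given as rounded lower bounds with the weaker level taken as 6, while counts, medians and orders use the deposited values. Differences are siKMO minus control on the log2 scale, and genes were counted at a difference of at least 2-fold in either direction. For 2-fold genes that had another probe set with a mean of at least 6, the share whose other probe sets all differed in the same direction by at least 1.5-fold was computed, with an exact binomial 95% interval, beside the same share among all such genes. Probe sets of one gene are not replicates of a culture: they test the measurement of a transcript, not the treatment.

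Before the data were examined, 35 gene lists, the settings and the rule for named genes were fixed. For each list with at least 5 measured members, the median difference was set against the medians of 10000 random lists of the same size, drawn from 20 bins of mean level. A list is said to stand apart where its median lay outside the central 95% of those random medians, as a description of this pair of arrays. Under this definition 1.5 of the 30 such lists would lie outside on average if each were a random list. Members of a list are co-regulated in any culture, so a list can stand apart between any pair of dishes. The genes named are KMO, the 12 highest and the 12 lowest differences, the 5 highest and the 5 lowest among genes whose 2 or more probe sets with a mean of at least 6 all differed in one direction by at least 1.5-fold, and up to 3 members of each list with the largest absolute difference. Members of the pluripotency, beta-catenin target, stem cell marker and kynurenine lists could all be named. Other genes named, such as the remaining 2-fold members of a list, were chosen after their values were seen.

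The calculation was tested on simulated data built on the levels of these arrays, with a noise SD of 0.15 on each array and 8986 genes in the step. All 85 measured genes simulated with a 3-fold difference were called at 2-fold in the right direction, 1 of 96 with a 1.5-fold difference was called, and 0 unchanged genes were called. Of 200 random lists, 9 lay outside the central 95%, and a list shifted by 0.3 lay at percentile 100. The simulated noise was assumed, since no replicate gives the true noise between cultures. The observed differences had an SD of 0.40 over probe sets at levels of 6 to 8 and 0.34 at levels of 8 to 14, noise and real differences together. Noise was drawn independently for each probe set. The simulation therefore tests the calculation and gives no rate of false calls between cultures or for co-regulated lists. Alternatives covered a minimum mean of 5 or 7, no minimum, a minimum on the higher array alone, the mean of all probe sets of a gene, omission of probe sets whose names end in _x_at or _s_at (which can bind several transcripts), centring on the median, quantile normalization of both columns, removal of a loess curve of the difference on the level (span 0.3), and thresholds of 1.5-fold and 3-fold. Under the alternatives 2000 random lists were drawn. Omission of list members shared with another list and a setting with levels under 6 taken as 6 were added after seeing the data. No array could be left out with 1 per group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.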

Results

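Per the labels, the series compared MDA-MB-231 cells 48 h after transfection with KMO siRNA (siKMO) and with a control siRNA. The array names carry the strings shLUC and shK421, usual for short hairpin constructs, so the construct used was not settled. MDA-MB-231 is an established line of triple-negative breast cancer, a type that lacks the hormone receptors and the amplified ERBB2 of other breast cancers. KMO encodes kynurenine 3-monooxygenase, a mitochondrial enzyme that converts kynurenine to 3-hydroxykynurenine on the route from tryptophan to NAD. The title of the study asks about pluripotency genes, beta-catenin and tumour progression. 1 array per condition was analysed, so there are no replicates, no difference below has a replicate check, and each describes this pair of cultures. Levels are RMA values on the log2 scale, and a difference of 1 is 2-fold.

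The knockdown target itself gave no usable signal. The 3 probe sets of KMO stood at 2.95, 2.37 and 2.11 in the control array and at 2.92, 2.51 and 2.35 in the siKMO array, differences of -0.03, 0.14 and 0.24. Genes of unrelated tissues such as liver, muscle and lens had a median level of 3.81 in the control array and 3.92 in the siKMO array, above all 3 KMO probe sets. KMO therefore lay at array background in both arrays, and its values neither check nor contradict the labels.

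RNA and labelling controls gave the following values. The level of the 3′ probe set of ACTB, a cytoskeletal actin, exceeded that of the 5′ probe set by 0.39 in the control array and by 0.33 in the siKMO array, and for the glycolytic enzyme GAPDH the values were -0.11 and -0.10. The 18 hybridisation spike-in probe sets differed between arrays by at most 0.17 and the 24 poly-A spike-in probe sets by at most 0.22. The 6 ribosomal RNA control probe sets had a median difference of 0.15 and a largest one of 0.85. Across all 54675 probe sets the levels correlated with Pearson r = 0.992, a correlation across probe sets, which are not independent replicates.

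Of 8997 measured genes, 77 were at least 2-fold higher and 125 at least 2-fold lower in the siKMO array. In 18 of the former and 29 of the latter the weaker array lay under 6; folds and differences of such genes or probe sets are given below as lower bounds, rounded, with the weaker level taken as 6, while counts use the deposited values. Ordered by the deposited difference, an order that is not settled where a level is under 6, the highest were RSAD2, the interferon-inducible antiviral enzyme viperin (5.65 in control, 8.06 in siKMO, at least 4.18-fold higher), SEMA3A, a secreted axon guidance factor (at least 2.13-fold), TFPI2, a secreted protease inhibitor (4.14-fold), HSD17B10, a mitochondrial dehydrogenase (4.10-fold), and IDO1, which opens the kynurenine pathway by oxidising tryptophan (5.48 and 7.46, at least 2.75-fold). They were followed by EREG, a ligand of the EGF receptor (5.94 and 7.77), CCNE2, a cyclin of S-phase entry (3.32-fold), STEAP1, a membrane protein of the STEAP family (3.29-fold), FN1, the matrix protein fibronectin (3.00-fold), TLR4, the lipopolysaccharide receptor (at least 1.92-fold), SPC24, a kinetochore component (2.98-fold), and CDC25A, a phosphatase that activates cyclin-dependent kinases (2.96-fold). The lowest were MMP1, interstitial collagenase (9.78 in control, 6.94 in siKMO, a 7.18-fold lower level), SPINK4, a secreted protease inhibitor family member (at least 5.70-fold lower), PSG5, a pregnancy-specific glycoprotein (at least 4.25-fold lower), and S100P, a calcium-binding protein (at least 4.75-fold lower). SUSD2 was at least 2.43-fold lower, DDIT4, a stress-induced inhibitor of mTORC1, was 3.88-fold lower, and CDH1, the adherens junction protein E-cadherin, was 3.78-fold lower (10.54 and 8.62). PSG9 and IL24 were 3.60- and 3.52-fold lower, and AQP3, a water and glycerol channel, CSPG4 and APOLD1 at least 3.59-, 2.37- and 2.26-fold lower. With levels under 6 taken as 6 throughout, 65 genes were higher and 111 lower by at least 2-fold.

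**Figure D1:**
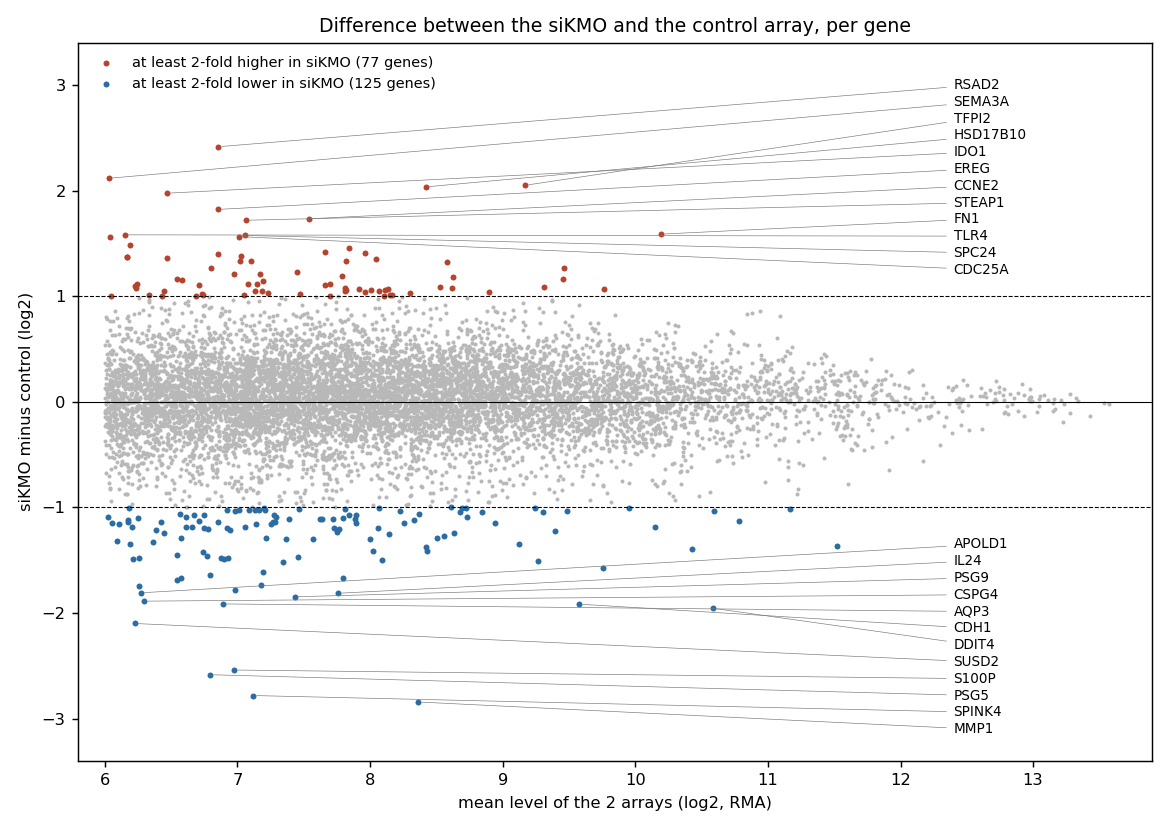
Difference between the siKMO and the control array (log2) against the mean level of both arrays (log2) for 8997 genes with a mean of at least 6, each point 1 gene and dashed lines at 2-fold. 77 genes lie above the upper line and 125 under the lower line, and names mark the 12 largest differences each way, from RSAD2 at 2.42 to MMP1 at -2.84, as deposited.

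Further probe sets were compared for the 2-fold genes. Of 69 such genes with a further probe set at a mean of at least 6, 57 (82.6%, exact binomial 95% interval 71.6% to 90.7%) had all others in the same direction by at least 1.5-fold, against 268 of 3777 genes (7.10%) when the gene was not chosen for its difference. The latter share is low by construction, since only 467 of 8997 genes were higher and 487 lower by 1.5-fold at all. In the order of their deposited differences, the highest genes with such backing were TFPI2 (2.01 to 2.05 over 2 probe sets), CCNE2 (1.73, and higher by at least 1.57 with the other probe set), FN1 (at least 1.47 with each of 4), GINS3, a subunit of the replicative helicase (higher by at least 0.93 and 0.85, with both control levels under 6), and MCM5, another helicase subunit (0.98 to 1.42). The lowest were CDH1 (-1.92, and lower by at least 0.95 with the other probe set, at 6.95 and 5.06), PSG9 (-1.86 to -1.85), PSG6 (-1.78, and lower by at least 1.37 with the other), IL1B, the cytokine interleukin-1 beta (-1.73 to -1.64), and SRGN, the granule proteoglycan serglycin (-1.57 to -1.50). PSG5 was at least 4.25-fold lower with one probe set and differed by -0.24 with the other, and the pregnancy-specific glycoproteins are near-identical paralogs, so their single values are uncertain. Without a minimum level the counts were 128 higher and 214 lower and the backed share was 35.9%, and at a minimum of 7 the counts were 51 and 77.

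For the genes named by the study's title, most pluripotency factors with a probe set lay under the level minimum and the others differed little. Of 25 listed genes, 22 had a probe set used here and the rest were not analysed here; 5 were measured, and 0 of the 5 differed by 1.5-fold. KLF4 differed by -0.53 (9.81 in control, 9.28 in siKMO), KLF5 differed by -0.32 and KLF2 by -0.15, all of them zinc finger transcription factors, while MYC and the DNA methyltransferase DNMT3B both differed by 0.11. SOX2 stood at 3.98 and 4.08 and NANOG at 3.64 and 3.76 in the control and siKMO arrays, near the median of the unrelated-tissue genes. The median of the list was -0.15, at percentile 13.96 of the matched random lists.

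Genes that beta-catenin switches on also showed no common direction. Of 11 measured targets, 7 were higher and 4 lower in the siKMO array, with BIRC5, the mitotic and anti-apoptotic protein survivin, at 0.60, the transcription factor SOX9 at 0.52, the receptor-clearing ligase ZNRF3 at 0.39 and FOSL1 at 0.36. DKK1, MYC and CCND1 differed by 0.13, 0.11 and 0.04 (0.45 with the other CCND1 probe set), and CD44, BMP4, PPARD and JUN by -0.12, -0.16, -0.16 and -0.29. JUN ran from -0.30 to 0.03 over 4 probe sets, so its direction was not settled, and CD44 from -0.65 to -0.05 over 8. The direct target AXIN2 was under the level minimum (5.26 and 5.17), as was LEF1 (5.13 and 5.73). The list median was 0.11 at percentile 75.4. CTNNB1, which encodes beta-catenin, stood at 10.93 and 11.02, a difference of 0.09 (-0.11 to 0.09 over 3 probe sets), and the 22 measured components of the Wnt pathway had a median of 0 at percentile 31.1, with the receptor FZD7 at -0.57, the transcription factor TCF7L2 at -0.52 and the ligase subunit BTRC at 0.39. These are RNA levels, and the amount and location of the beta-catenin protein were not measured.

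Breast cancer stem cell markers were lower as a group. Of 11 measured markers, 10 were lower in the siKMO array and 2 of them by at least 2-fold: the integrin ITGB3 (6.63 and 5.48, at least 1.55-fold lower with the weaker level taken as 6) and the surface glycoprotein CD24 (10.46 and 9.45, 2.01-fold lower). The adhesion molecule EPCAM differed by -0.90, ITGB1 by -0.41, ALDH1A3 by -0.29, ITGA6 by -0.25, PROCR by -0.19, NOTCH1 by -0.15 and CD44 by -0.12, the drug transporter ABCG2 was lower by at least 0.51 (6.51 and 5.98), and SOX9 alone was higher. The chemokine receptor CXCR4 was 7.20 in the control array and 4.41 in the siKMO array, but its mean was under the minimum. Its other probe sets, also under it, stood at 6.49 and 4.78 and at 6.37 and 5.21. With 6 in place of the siKMO levels the differences were -1.20, -0.49 and -0.37 in that order. The median of -0.29 lay at percentile 0.25. Without probe sets ending in _x_at or _s_at the percentile was 2.83, inside the central 95%. High CD44 with low CD24 is the usual surface profile of such cells, so CD24 in this list does not mark them by a high level.

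In the kynurenine and NAD pathway, IDO1 was at least 2.75-fold higher, with its control level of 5.48 under 6, and the values of its 12 other measured genes differed by less than 2-fold. NAPRT was higher by at least 0.29 (5.93 and 6.29). GOT2, WARS1 and the amino acid transporter SLC7A5 differed by 0.35, 0.28 and 0.24, and NADSYN1 and SLC3A2 by 0.10 and -0.04. NMNAT2 and NAMPT, which make NAD from nicotinamide and its mononucleotide, differed by -0.65 and -0.57 (-0.65 to -0.25 over 3 probe sets and -1.08 to -0.57 over 4), the kynurenine aminotransferases KYAT1 and KYAT3 by -0.52 and -0.28, kynureninase (KYNU) by -0.23 and NMNAT1 by -0.15. The list median was -0.04 at percentile 21.4. Of the targets of the aryl hydrocarbon receptor, which kynurenine can bind, 4 were measured, too few for a percentile; TIPARP differed by -0.37 and NQO1 by -0.01, and probe sets of CYP1B1 ran from -0.29 to 0.08 and those of NFE2L2 from -0.19 to 0.14.

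Genes of the G1/S transition were higher throughout. All 23 measured members were higher in the siKMO array, 10 of them by at least 2-fold, led by CCNE2 (6.67 and 8.41), MCM5 (6.95 and 8.37) and MCM4 (7.37 and 8.72), the last pair being subunits of the helicase that opens DNA at replication origins. The transcription factor E2F1 differed by 0.71 and the replication clamp PCNA by 0.57. The median of 0.91, a 1.88-fold higher level, exceeded those of all 10000 matched random lists, whose central 95% ran from -0.12 to 0.18. Genes of G2 and mitosis differed less: 22 of 25 were higher, 0 by 2-fold, with BIRC5 at 0.60, the kinase AURKB at 0.47 and the spindle checkpoint protein CDC20 at 0.41, and the median of 0.15 lay at percentile 94.0. CDK1 differed by 0.04. Probe sets of the proliferation marker MKI67 ran from -0.003 to 0.78 and those of CCNA2 from -0.26 to 0.02, so neither gene had a settled difference.

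Genes of the integrated stress response, the program by which ATF4 answers amino acid shortage and related stresses, were lower. Of 18 measured members, 17 were lower in the siKMO array and 5 by at least 2-fold: DDIT4 (11.57 and 9.61), the transcription factor ATF3 (7.62 and 6.14, and lower by at least 0.77 with its other probe set), the glutathione-degrading enzyme CHAC1 (a difference of -1.46), VEGFA, the angiogenic growth factor (10.74 and 9.56), and DDIT3, the transcription factor CHOP, at -1.10. ATF4 itself differed by -0.27. The median of -0.68 lay under those of all 10000 random lists. The 16 chaperones and partners of the endoplasmic reticulum, which mark another branch of the stress response, had a median of -0.05 at percentile 14.04, with SDF2L1 at 0.56, XBP1 at -0.29, DNAJB9 at -0.28 and the chaperone HSPA5 at -0.06.

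Hypoxia and glycolysis genes were lower as well. Of 22 measured, 21 were lower and 5 by at least 2-fold: the aldolase ALDOC (6.80 and 5.61, or at least 1.74-fold), VEGFA, the MYC antagonist MXI1 (9.52 and 8.37), the glucose transporter SLC2A3 at -1.07 and NDRG1 at -1.04. The highly expressed glycolytic enzymes LDHA and PGK1 differed by -0.11 and -0.14, although PGK1 was lower by at least 0.46 with another of its 6 probe sets. The median of -0.60 lay under those of all random lists, and with the mean of all probe sets of a gene it was -0.27. Nuclear genes of oxidative phosphorylation, the mitochondrial respiratory machinery, had a median of 0.21 at percentile 99.7, with 18 of 21 higher, 0 by 1.5-fold, and ATP5PO at 0.40, NDUFS3 at 0.39 and COX5A at 0.37. With the mean of all probe sets of a gene that percentile was 94.2.

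Inflammatory genes that NF-kappaB controls were lower in 11 of 15 measured cases, with a median of -0.60 under those of all random lists (-0.36 without a minimum level). IL1B (8.05 and 6.31), the cytokine IL11 (8.27 and 7.16, with its other probe set at -0.42) and the chemokine CCL5 (6.68 and 5.68, or at least 1.60-fold) were lower by at least 2-fold, and IL6 differed by -0.62. The chemokine CXCL1 went the other way at 0.73. Immediate early genes of MAPK signalling were lower in 17 of 20 cases with a median of -0.37 at percentile 0, led by EGR1 (-1.15), JUNB (-0.85) and the ERK phosphatase DUSP6 (-0.79). Type I interferon response genes showed no common direction: 14 of 29 were higher and 15 lower, with RSAD2 higher by at least 2.06, the helicase DDX60 at -1.09 and IFI27 at -0.95, and the median was -0.02 at percentile 18.4. With the mean of all probe sets of a gene it was -0.15 at percentile 0.4. The 13 antigen presentation genes had a median of 0.02 at percentile 44.6, with the immunoproteasome subunits PSMB10 and PSMB9 at 0.67 and 0.51 and the peptide transporter TAP2 at 0.16 to 0.54 over 3 probe sets.

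Epithelial genes were lower while mesenchymal genes went both ways. Of 13 measured epithelial genes, 11 were lower and 5 by at least 2-fold: CDH1, the protease inhibitor SPINT1 (7.64 and 6.15), the tight junction protein occludin, OCLN (9.11 and 7.73), CLDN7 at -1.11 and SPINT2 at -1.03. The keratins KRT8 and KRT18 differed by 0.17 and 0.15. The median of -0.54 lay under those of all random lists. Among 10 mesenchymal genes the median was -0.09 at percentile 11.1; FN1 was 3.00-fold higher and SNAI2 differed by 0.69, whereas the cadherin CDH11 was at -0.95 and the collagen cross-linking enzyme LOX at -0.84 (-0.31 with its other probe set), and VIM, which encodes vimentin, differed by 0.06 (higher by at least 0.48 with its other probe set). Across the alternatives the mesenchymal median ran from -0.19 to 0.25, so its sign was not settled. Proteases of invasion and their inhibitors were lower in 11 of 14 cases with a median of -0.37 under all random lists, led by MMP1, ADAM10 (-0.89) and the plasminogen activator PLAT (-0.87).

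Breast cell type markers were lower in part. Of 9 luminal markers, 3 were lower by at least 2-fold, AGR2 (8.63 and 6.96), the transcription factor SPDEF (7.25 and 6.06, and -1.19 to -0.64 over 3 probe sets) and the receptor ERBB3 (6.73 and 5.61, or at least 1.66-fold), with a median of -0.29 at percentile 0.78. The median was 0.04 at a minimum level of 7. Of 9 basal markers, the cadherin CDH3 (3.05-fold) and the integrin ITGB4 (2.10-fold) were lower by at least 2-fold, LAMB3 differed by -0.77, and the median of -0.14 lay at percentile 4.10. Without probe sets ending in _x_at or _s_at it was -0.39 at percentile 0.5. Fibroblast and endothelial markers had 2 measured members each, COL6A3 at -0.68 and COL1A1 at -0.18, and ESAM at -0.998 and EGFL7 at -0.20, and 0 of the immune cell markers reached the minimum.

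**Figure D2:**
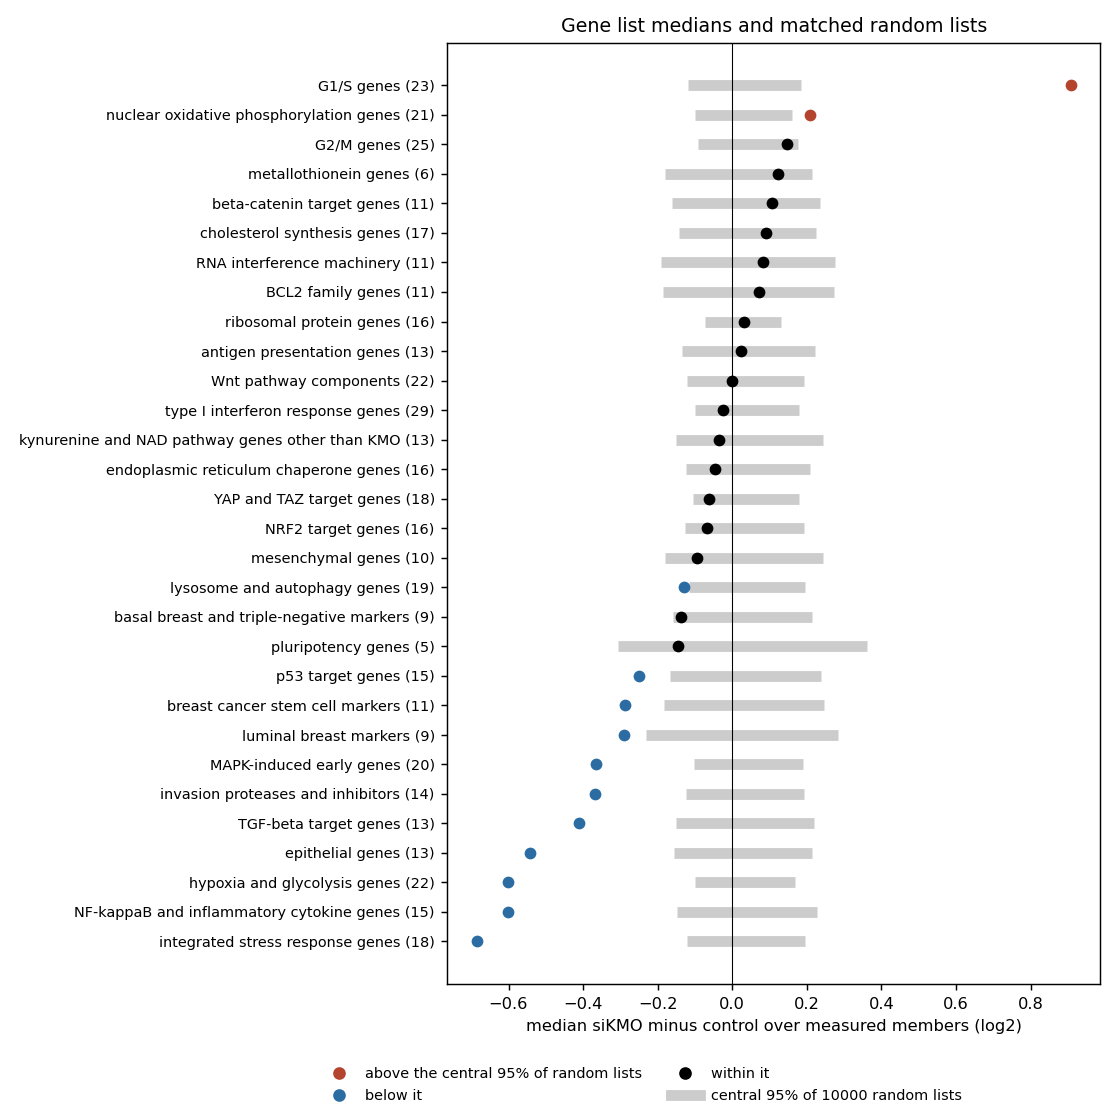
Median difference siKMO minus control (log2) of the 30 gene lists with at least 5 measured members, whose number stands in brackets, with grey bars for the central 95% of 10000 random lists matched on level. G1/S genes lie at 0.91 and integrated stress response genes at -0.68, the outermost lists on either side.

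Further lists stood apart less firmly. Targets of TGF-beta had a median of -0.41 under all random lists, with the differentiation inhibitor ID2 at -1.25 and BHLHE40 at -0.87, yet without probe sets ending in _x_at or _s_at the median was 0.42 at percentile 99.5, on the opposite side. Targets of p53 had a median of -0.25 at percentile 0.36 with 8 lower and 7 higher, GDF15 at -1.30 and TP53INP1 at -1.02 against the nuclease AEN, higher by at least 0.45 (5.68 and 6.45). CDKN1A differed by -0.73, and MDM2 was higher by 0.54 with one probe set and lower by at least 0.11 with the other. At a minimum level of 5 the median was -0.09 at percentile 10.8. Lysosome and autophagy genes had a median of -0.13 at percentile 1.78, with GABARAPL1 at -0.66, ATP6V0D1 at 0.63 and GLA at 0.60, and lay inside the central 95% at a minimum of 7 and without shared members.

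The remaining lists lay within the central 95% of random lists. YAP and TAZ targets had a median of -0.06 at percentile 7.99, with IGFBP3 at 1.12 and FJX1 at 0.88, and NRF2 targets one of -0.07 at percentile 9.78, with the cystine transporter SLC7A11 at -0.86. BCL2 family genes had a median of 0.07 at percentile 58.6, with PMAIP1 at -0.58 and BCL2L1 at -0.57, and cholesterol synthesis genes one of 0.09 at percentile 67.7, with NSDHL at 0.67. The RNA interference machinery had a median of 0.08 at percentile 61.9, with DICER1 at -0.70, AGO1 at 0.68 and DROSHA at 0.62. Metallothionein genes had a median of 0.12 at percentile 84.1 and ribosomal protein genes one of 0.03 at percentile 55.4. Of the 30 lists with a percentile, 11 lay under and 2 above the central 95%.

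**Figure D3:**
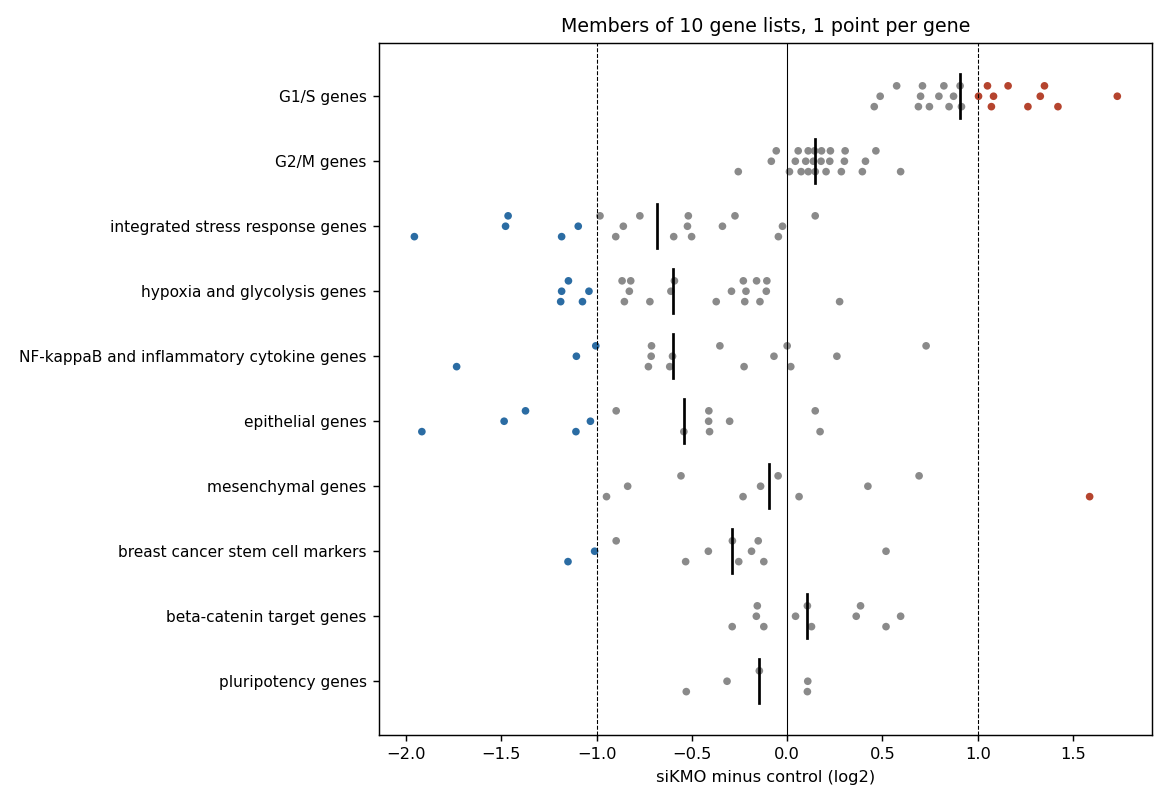
Difference siKMO minus control (log2) of each measured member of 10 gene lists, 1 point per gene, black bars at the list medians and dashed lines at 2-fold. All 23 G1/S genes lie to the right of 0, from 0.46 to 1.73, and 17 of 18 integrated stress response genes lie to the left.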

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

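Of the tests below, those of the loess curve were written before their result was seen, and the tests of cycling cells, admixed cells, second probe sets and other interferon genes were chosen after the result was seen.

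Signal appeared in probe sets that the comparison does not use. Among 1189 probe sets that the platform annotation used here does not list, at a mean of at least 6, 17 were at least 2-fold lower and 3 at least 2-fold higher in the siKMO array. The largest differences were -2.13 and 2.05. They are reported as values, with no gene named.

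Replication genes were higher and hypoxia and stress genes lower in the siKMO array. With a loess curve of the difference on the level removed, the G1/S median was 0.86 (0.91 before) and the hypoxia median -0.64 (-0.60 before). A smooth scaling difference left in the deposited values was thus too small to give these medians. The sorted values of both columns were already nearly alike, so little was left to remove. Both medians stayed outside all random lists, but those were matched on level, so this does not bear on such scaling. The G1/S median exceeded the G2/M median by 0.76 (bootstrap 95% interval over members 0.60 to 0.94), so a cause that lifts both lists alike is argued against. The interval covers the spread between genes, not between cultures. That a larger share of cycling cells lifts both lists alike was assumed, not tested. As 22 of 25 G2/M genes were also higher, such a larger share is not excluded. A larger share of cells in S phase, or a dish with fresher medium or fewer cells, stays open as well, since each condition was 1 culture and culture and knockdown have the same split. An effect of the KMO siRNA on entry into S phase, through KMO or off-target, is a hypothesis that these arrays leave untested. KMO lay at array background in both arrays, so whether its RNA was lowered could not be checked.

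Of 13 measured epithelial genes, 11 were lower in the siKMO array, CDH1 among them, although KRT8 and KRT18 were not. MDA-MB-231 is usually described as having little E-cadherin. Yet CDH1 RNA stood at 10.54 in the control array and 8.62 in the siKMO array, both far above the unrelated-tissue medians of 3.81 and 3.92. Both arrays thus depart from that description, and the reason was not tested. An error of a single CDH1 probe set is argued against by the other probe set at -1.89, although its siKMO level of 5.06 is under 6 and with 6 in its place the difference is only -0.95. A smaller admixture of epithelial cells cannot be told apart from a change within the cells: the epithelial regulators ESRP1, GRHL2 and RAB25 reached 3.59 at the highest in the control array, below the 3.81 median of unrelated-tissue genes, but genes at background exclude nothing and no profile of such cells was used. A change in epithelial genes with the KMO siRNA, through KMO or off-target, stays open as an untested hypothesis. The knockdown itself could not be checked, with KMO at array background.

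RSAD2, CMPK2 and IDO1, each of which interferon can induce, were higher in the siKMO array. CMPK2 stood at 3.85 and 5.89, both under 6, and was named after its values were seen. An error of a single RSAD2 probe set is argued against by the other at 2.26, although its mean of 5.62 is under the minimum and with 6 in place of its control level of 4.49 the difference is only 0.75. The 28 other measured type I interferon response genes had a median of -0.038 (bootstrap 95% interval over members -0.24 to 0.19). A response to the transfected RNA that lifts them all alike is argued against. A response of only some interferon genes stays open, and the interval covers the spread between genes, not between cultures. An off-target effect of the siRNA and an effect of the knockdown on RSAD2, CMPK2 and IDO1 stay open and were not tested.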

How the results depend on the processing

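The omission of shared list members and the setting of levels under 6 to 6 were chosen after the result was seen; the other alternatives were fixed before the data were examined. Of 313 comparisons of a list with an alternative, 298 kept the list on its side of the central 95% and 15 did not. Of 1903 comparisons of named genes, 69 moved by more than 0.16, the SD between probe sets of a gene. The 2-fold counts of 77 higher and 125 lower genes became 128 and 214 without a minimum, 51 and 77 at a minimum of 7, 46 and 67 with the mean of all probe sets, 467 and 487 at 1.5-fold and 9 and 20 at 3-fold, and the lower count became 79 without probe sets ending in _x_at or _s_at. A minimum or threshold admits more or fewer genes by construction; for both alternatives that alter which probe sets enter, the cause was not tested. With levels under 6 set to 6 they were 65 and 111, all among the main ones. The share of 82.6% of 2-fold genes backed by other probe sets became 69.4% at a minimum of 5, 91.4% at 7, 35.9% with no minimum and 63.2% without those probe sets. The TGF-beta target median of -0.41 turned to 0.013 with the mean of all probe sets and to 0.42 without probe sets ending in _x_at or _s_at, the luminal median of -0.29 turned to 0.037 at a minimum of 7, and the YAP and TAZ median was -0.023 with the mean of all probe sets; the cause was not tested. G1/S, integrated stress response, hypoxia, NF-kappaB, epithelial, invasion and MAPK lists, 7 of the 13 lists outside the central 95%, stayed outside on the same side under all alternatives run; their medians ran from 0.86 to 0.96, -0.71 to -0.52, -0.77 to -0.27, -0.65 to -0.36, -0.83 to -0.41, -0.40 to -0.29 and -0.41 to -0.32 in that order. Stem cell marker (2.83), p53 target (10.8 at a minimum of 5, 3.0 with the mean of all probe sets), oxidative phosphorylation (94.2), lysosome (4.15 at a minimum of 7, 5.98 without shared members), TGF-beta target (14.2 at a minimum of 7, 36.0 with the mean of all probe sets) and luminal lists (48.1 at a minimum of 7) reached these percentiles inside the central 95%. Without probe sets ending in _x_at or _s_at the TGF-beta list lay on the opposite side, at 99.5. Lists that lay inside the central 95% and left it were interferon response (0.4 with the mean of all probe sets), G2/M (97.55 without a minimum), mesenchymal (1.6 without a minimum) and basal markers (0.5 without probe sets ending in _x_at or _s_at, and 0.5 without shared members). No value exists for KMO without _x_at or _s_at probe sets, since all of its probe sets end that way. No paired analysis was possible because each group has 1 array. Levels near background limit KMO, SOX2 and NANOG.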

Other observations

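The test of neighbouring genes was written before its result was seen, and the genes in the next 2 paragraphs were chosen after their values were seen.

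TXNIP, which restrains glucose uptake, and its relative ARRDC4, both known targets of a glucose-sensing transcription factor, were lower in the siKMO array by 2.58-fold (12.21 and 10.84) and at least 1.82-fold (6.86 and 5.51). SAT1, which acetylates polyamines for breakdown, was 2.63-fold lower, the cyclin-dependent kinase inhibitor CDKN1C 2.35-fold, the nuclear receptor coactivator PNRC1 2.44-fold, the transcription factor KLF9 at least 2.10-fold, YPEL2 2.78-fold, YPEL3 2.46-fold, and CREBRF and TSC22D3 2.03- and 2.02-fold. Beyond the fixed G1/S list, the replication and cohesion genes MCM10, DSCC1, ESCO2, EXO1, PRIM1 and TIPIN were 2.52-, 2.52-, at least 2.22-, 2.31-, 2.15- and 2.03-fold higher.

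LTB, a lymphotoxin chain, was 2.82-fold lower and the integrin chain ITGB2 2.31-fold lower, whereas the receptor TLR4 was at least 1.92-fold higher. The 13 immune cell markers with a probe set all stayed under a mean of 6. INHBA, an activin subunit, differed by 1.32, and NNMT, which methylates nicotinamide, was 2.34-fold lower (10.01 and 8.78). IL1A stood at 6.86 and 4.50 and CCL2 at 2.90 and 5.07, both with a mean under the minimum. Among 770 probe sets listed with several genes at a mean of at least 6, 10 were at least 2-fold lower and 0 higher.

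RSAD2 and CMPK2 lie next to each other in the genome, as do CDH1 and CDH3, so the hypothesis tested was that genes that are next to each other share their difference. Of 8650 adjacent pairs of measured genes, gene families left out, 2 were at least 2-fold different in the same direction, TCEA3 with ASAP3 and TFPI2 with GNG11. Shuffled gene orders gave a median of 2 pairs and a central 95% that reached 6, so the count did not exceed that of chance. CMPK2 is under the minimum level and its pair with RSAD2 was not counted. The pair of CDH1 with CDH3 was left out as a family, taken as symbols that begin with the same letters. The count therefore does not bear on either pair.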
